A study of Mus musculus with 6 samples.

How the data were processed

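Poly(A)-selected RNA of 6 samples of a mouse leukaemia cell line, 3 treated with PBS as vehicle and 3 with 4'-O-methylpyridoxine (OMP), was sequenced after Illumina TruSeq library preparation, per the labels' protocols. The deposited values are RPKM, reads scaled to gene length and to the library total, in a table with 1 column per library and 53465 Ensembl gene identifiers. The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.36, STAR 2.5.3a and featureCounts 1.6.3 with the mouse build mm10, also called GRCm38. The annotation release, the strand setting and the filters of the counting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be separated further. Each column was matched to its library by the title in the labels, and groups were taken from the labels.

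The RPKM values kept the steps of whole reads. For the 19970 genes above 0 in any library, a gene length and a library total were found for which 100% of the values came out as whole reads within a relative tolerance of 1e-06. These lengths equalled an annotated transcript for 94.6% of the genes. The library totals recovered in this way ran from 3494986 to 4247619 reads, and 3 reads of a gene of 1 kb stood for an RPKM of 0.706 to 0.858. Depth limits the precision of low genes, and reads without molecular identifiers are not independent molecules, so read counts and intervals given here cover counting error only. Gene positions, biotypes and GC content came from GENCODE release M21 on GRCm38, which held 53360 of the identifiers. That release may not be the one used for the counting.

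The main comparison was OMP against Vehicle over all 6 libraries with limma 3.58.1 in R 4.3.3. Genes with an RPKM of at least 1 in at least 3 of the 6 libraries were kept, log2(RPKM + 0.5) was fitted with a linear model without covariates, and the two-sided moderated test used a prior variance that followed the mean expression. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. A log2 fold change is on the log2(RPKM + 0.5) scale and understates the change of low genes, as do the folds made from it. RPKM values are given as mean ± SD (n = 3 per group) and log2 fold changes with their standard error (SE). The labels do not say whether replicates came from separate cultures or passages, so p-values measure the spread between these libraries, which may be technical.

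In total 38 gene lists were fixed before the data were examined, 8 on vitamin B6, its enzymes and the leukaemic and maturation programmes, 19 on other pathways, 7 on markers of other blood cells and 4 on RNA quality and handling. Each list was tested with camera at a preset correlation of 0.01 between genes, two-sided and adjusted over the 38 lists, beside camera with an estimated correlation and the fry test. Of the 1084 listed entries, 2 matched no row of the table and were not analysed here. Named genes were chosen by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls among genes past the threshold with a mean RPKM of at least 5 in the higher group and no overlap between groups, leaving out gene models named Gm with digits, Rik clones and pseudogenes. It also took a few genes fixed by name, among them Pdxk, Odc1, Myc, Hoxa9 and Meis1, whatever their values, and the 2 members with the smallest p-value in each of the 8 lists on the main question and in every other list called by camera. This gave 48 genes, some of which are not reported here. Other genes are said to be chosen after their values were seen.

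The procedure was tested on simulated data for OMP against Vehicle with 11100 genes tested. It recovered 10.8% of 65 genes changed 1.25-fold, 57.8% of 64 changed 1.5-fold and 84.4% of 64 changed 2-fold, and 6.67% of its calls were false. The simulation changed 200 genes at a fixed dispersion of 0.002, while the real comparison called 4735. The adjusted threshold depends on the share of changed genes, so these percentages do not carry over to the real data. A simulated shift of 1 list was called and 0 other lists were called. Genes were simulated independently of each other, so this does not test how camera behaves where the genes of a list are correlated.

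Alternatives chosen before the data were examined were pseudocounts of 1 and 0.1, no filter and a filter at an RPKM of 5, rescaling to TPM, median-of-ratios scaling, quantile normalization, a robust prior, the replicate number as a block, stricter thresholds and leaving out each library in turn. Alternatives added after seeing the data were limma-voom on the recovered reads, reads thinned to equal totals, leaving out features under 200 bp, and removal of the trend with GC content and length. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 1.19 to 1.61, so none was counted as a duplicate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.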

Results

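The transcriptome of Nras(G12D)/MLL-AF9 cells, a mouse leukaemia line that carries a mutant Nras and the fusion of Kmt2a with Mllt3, was measured after 6 days with 100 µM OMP or with PBS as vehicle. OMP, also known as ginkgotoxin, is an analog of vitamin B6 and a known inhibitor of pyridoxal kinase, the product of Pdxk. Each group had 3 libraries. Library totals recovered from the RPKM values were 3737843, 4091358 and 4247619 reads for Vehicle replicates 1 to 3. For OMP replicates 1 to 3 they were 3494986, 3551983 and 3720117 reads. Reads recovered for genes made up 99.8% to 99.9% of these totals, so they do not give the number of reads sequenced. The comparison asks which transcripts differed between OMP-treated and vehicle-treated cells.

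OMP-treated cells held more mRNA of several neutrophil granule and stefin genes and less mRNA of genes for DNA replication and mitosis. Retnlg, a neutrophil-secreted resistin-like protein, rose 16.2-fold from 3.50 ± 1.16 to 62.7 ± 7.02 RPKM, and S100a9, a calcium-binding protein of neutrophils, rose 3.98-fold from 1372 ± 9.43 to 5462 ± 143 RPKM. The desaturase genes Scd1 and Fads2 fell, Scd1 from 5.96 ± 0.937 to 0.307 ± 0.146 RPKM and Fads2 from 64.2 ± 2.64 to 14.8 ± 0.350 RPKM. Irf8, a transcription factor of the monocyte and dendritic lineages, was 5.26-fold lower. Of 11020 genes tested with limma, 4735 passed the threshold, or 43.0%, of which 1702 were higher and 3033 lower with OMP. A change of at least 2-fold was seen for 180 higher and 244 lower genes, and the median size of the log2 fold change among changed genes was 0.43. In 6004 genes (54.5%) the values of the groups did not overlap, where chance gives 10%. The split between higher and lower genes depended on scaling. With median-of-ratios scaling 2370 genes were higher and 2237 lower, with quantile normalization 2244 and 2321, with TPM rescaling 1215 and 3973, and with the trend with GC content and length removed, chosen after seeing the data, 2472 and 2162.

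**Figure D1:**
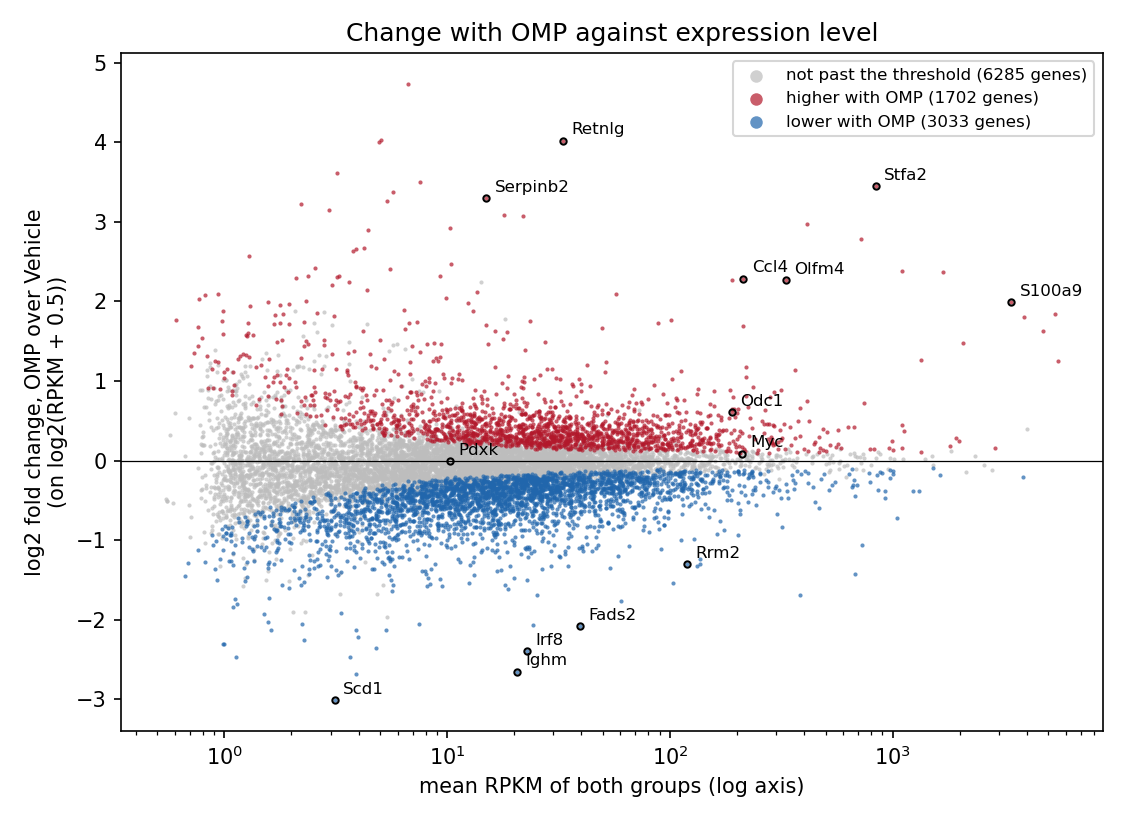
Log2 fold change of each of the 11020 genes tested (vertical axis, OMP over Vehicle) against its mean RPKM over both groups (horizontal log axis), with 1702 higher genes in red, 3033 lower genes in blue and the rest in grey. Circles mark named genes, with Retnlg at 4.02 and Scd1 at -3.01.

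Among the 8 largest rises were Retnlg (ENSMUSG00000022651, GRCm38 chromosome 16, 48872621 to 48874496, log2 fold change 4.02 ± 0.20 SE, limma adjusted p = 3.40e-06) and Serpinb2 (chromosome 1, 107511423 to 107535478), a plasminogen activator inhibitor, which rose 9.87-fold to 27.6 ± 1.85 RPKM. Asprv1, an aspartic protease gene, rose 8.91-fold from 0.216 ± 0.240 to 5.65 ± 0.403 RPKM, with 4 reads in Vehicle and 94 in OMP. With so few Vehicle reads this fold depends on the pseudocount, and the ratio of the mean RPKM values was 26.2. Stfa2 (chromosome 16, 36403992 to 36408457), a stefin A cysteine protease inhibitor, rose 10.9-fold from 140.4 ± 5.68 to 1540 ± 64.6 RPKM, and BC117090 of the same gene cluster rose 8.48-fold. Members of this cluster are near-identical copies, so the share of reads given to each is uncertain. The remaining rises were at short RNA genes with few reads in poly(A)-selected libraries. Reads of overlapping transcripts cannot be separated from theirs, so a rise of the short RNAs themselves is not shown. Mir6924, a microRNA gene of 63 bp, had 0 reads in Vehicle and 7 in OMP, a ratio of 2.62 against an assumed floor of 3 Vehicle reads. That ratio leaves out the counting error of the OMP reads, so it is not a lower limit. Most of those reads came from OMP replicate 3 (21.3 RPKM, against 4.54 and 4.47 in replicates 1 and 2). Snord73a had 1 and 10 reads, a ratio of 11.2 with an exact 95% counting interval from 1.596 to 487, and Snord49b had 1 and 8 reads, a ratio of 8.97 with an interval from 1.20 to 398. Snord73a passed the threshold in the main test (adjusted p = 0.0121) but not with a robust prior in limma (adjusted p = 0.0617).

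The 8 largest falls included Scd1, Ighm, Irf8, Nkg7, Cnn3, Rassf4 and Fads2. Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879) had a log2 fold change of -3.01 ± 0.22 SE (limma adjusted p = 2.70e-05). Fads2 (chromosome 19, 10062765 to 10101746) was 4.23-fold lower. Ighm, the constant region of the immunoglobulin mu chain, dropped from 36.0 ± 1.93 to 5.32 ± 0.492 RPKM. Irf8 (chromosome 8, 120736358 to 120756694) went from 38.6 ± 2.02 to 6.96 ± 0.754 RPKM. Nkg7, Cnn3 and Rassf4 were 5.13-fold, 4.66-fold and 4.39-fold lower.

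The mRNA of the known target of OMP did not pass the threshold. Pdxk (ENSMUSG00000032788, chromosome 10, 78436744 to 78464975) stood at 10.3 ± 0.165 RPKM in Vehicle and 10.3 ± 0.718 RPKM in OMP, with a log2 fold change of -0.01 ± 0.08 SE (limma adjusted p = 0.965). Slc19a2, a thiamine transporter also linked to pyridoxine uptake, rose 1.43-fold. Plpbp, a pyridoxal phosphate-binding protein chosen after its values were seen, had a log2 fold change of 0.24 ± 0.09 SE (limma adjusted p = 0.0530). Of 4 tested members of the vitamin B6 list 2 rose and 0 fell, or 3 and 0 when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.0721). It passed without a filter on low values (0.0375) and with quantile normalization (0.0476).

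Enzymes that use pyridoxal phosphate moved in both directions. Odc1, ornithine decarboxylase, rose 1.53-fold from 149.5 ± 5.81 to 228.8 ± 5.26 RPKM, while Gpt2, an alanine aminotransferase, was 1.62-fold lower. Of 30 tested enzymes 6 rose and 9 fell, or 6 and 12 when adjusted over the list alone, and the list as a set was not called (camera adjusted p = 0.796).

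Genes of polyamine metabolism included several that rose. Smox, spermine oxidase, rose 3.07-fold from 8.82 ± 0.681 to 28.1 ± 2.67 RPKM, and Srm, spermidine synthase, rose 1.86-fold. Of 18 tested genes 7 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0229). The call was lost with an estimated correlation (adjusted p = 0.188) and without Vehicle replicate 3 (adjusted p = 0.0514), and the list median of 0.08 was -0.00074 with TPM rescaling.

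**Figure D2:**
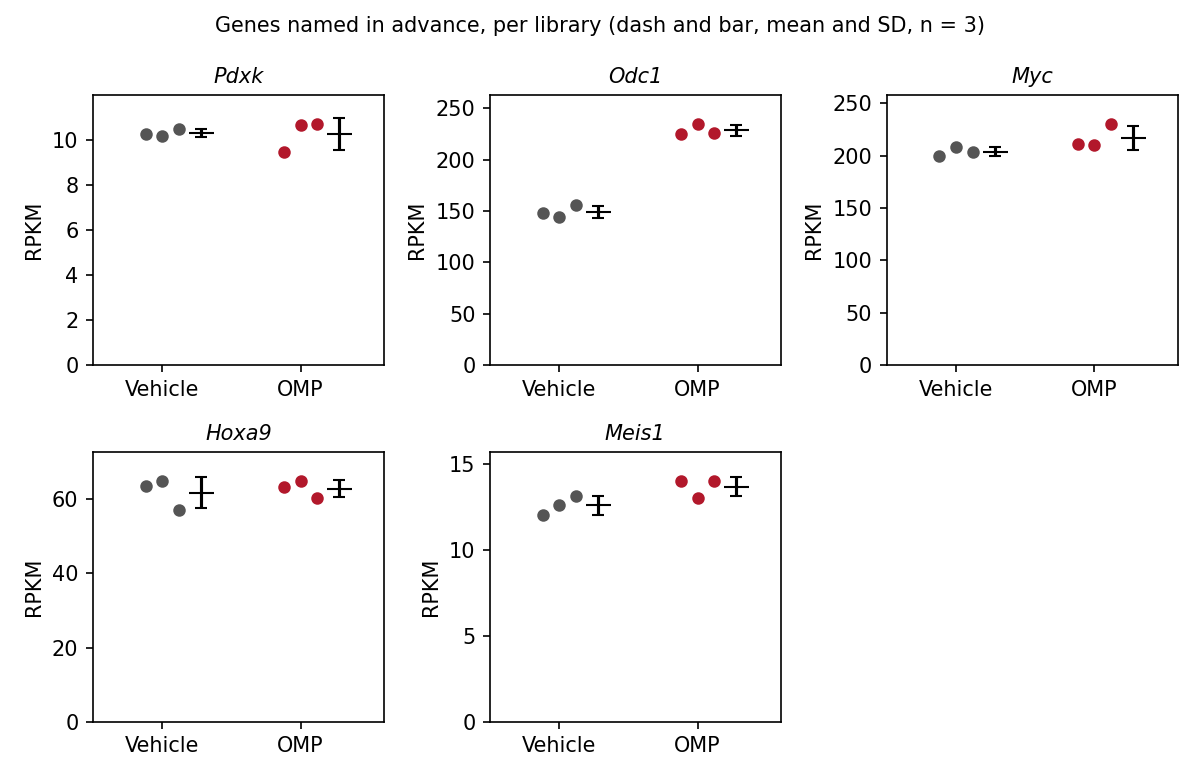
RPKM of Pdxk, Odc1, Myc, Hoxa9 and Meis1 in each library (points) with the mean and SD of 3 libraries per group (dash and bar), each axis starting at 0. Odc1 was higher in all 3 OMP libraries than in any Vehicle library, and Pdxk averaged 10.3 RPKM in both groups.

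Genes of DNA replication and mitosis fell nearly throughout. Rrm2, a subunit of ribonucleotide reductase, was 2.46-fold lower (169.7 ± 2.20 to 68.6 ± 1.95 RPKM), and Cdt1, a replication licensing factor, was 2.14-fold lower. The mitotic kinase gene Aurkb was 2.08-fold lower and Cdca3 1.93-fold lower. Of 49 tested G1/S and replication genes 0 rose and 47 fell, or 48 when adjusted over the list alone, with a median log2 fold change of -0.65 (camera adjusted p = 1.05e-14). Of 50 G2/M genes 0 rose and 44 fell, or 45 when adjusted over the list alone, with a median of -0.56 (camera adjusted p = 1.67e-12). Both calls held with an estimated correlation (adjusted p = 0.0153 for each).

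MYC target genes, mainly of ribosome assembly and nucleolar function, rose on balance. Nop56, a nucleolar protein, rose 1.74-fold from 140.6 ± 3.40 to 245.0 ± 6.52 RPKM, and Tfrc, the transferrin receptor, rose 1.78-fold from 67.0 ± 0.324 to 119.9 ± 2.75 RPKM. Of 50 tested targets 29 rose and 9 fell, or 30 and 9 when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 2.78e-07, and 0.0375 as adjusted p with an estimated correlation). Myc itself had 203.8 ± 4.18 RPKM in Vehicle and 217.0 ± 11.6 RPKM in OMP (limma adjusted p = 0.137). It passed the threshold with median-of-ratios scaling, at a log2 fold change of 0.18 (limma adjusted p = 0.0107).

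Granulocyte genes split into groups. Olfm4, a specific granule protein, rose 4.81-fold from 113.9 ± 0.863 to 550.4 ± 7.96 RPKM. Of the genes chosen after their values were seen, Ltf (lactoferrin) rose 6.40-fold and Ngp (neutrophilic granule protein) had a log2 fold change of 2.27 ± 0.05 SE. Mpo (myeloperoxidase) and Elane (neutrophil elastase), which are azurophil granule proteins, fell by 2.05 and 1.43 on the log2 scale. Of 35 tested genes 21 rose and 8 fell, or 22 and 8 when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 1.04e-05). The call was lost with an estimated correlation (adjusted p = 0.198).

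**Figure D3:**
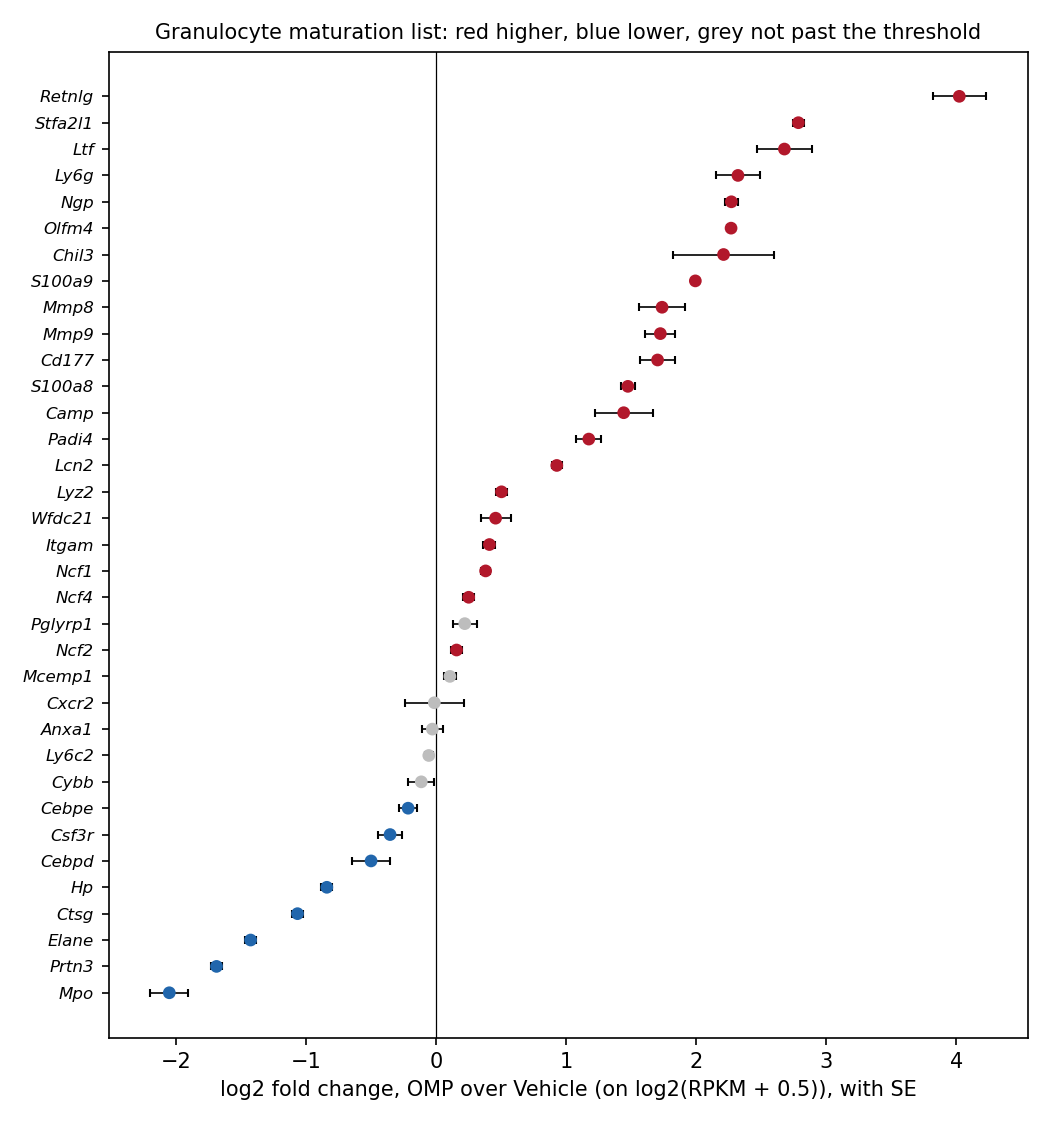
Log2 fold change (OMP over Vehicle) with its SE for the 35 tested genes of the granulocyte list, red where higher, blue where lower and grey where not past the threshold. Retnlg lies highest at 4.02 and Mpo lowest at -2.05.

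Monocyte and macrophage markers changed in both directions. Cd14, the lipopolysaccharide co-receptor, rose 3.17-fold from 23.6 ± 1.02 to 76.0 ± 2.64 RPKM, while Irf8 fell. Of 21 tested markers 9 rose and 5 fell, with the same counts when adjusted over the list alone, and the list was not called (camera adjusted p = 0.236), although it was without a filter on low values (0.0304).

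The genes of the leukaemic programme moved in both directions. Hoxa9 (log2 fold change 0.03 ± 0.06 SE, limma adjusted p = 0.750) and Meis1 (0.12 ± 0.07 SE, limma adjusted p = 0.221) did not pass the threshold. Meis1 passed with median-of-ratios scaling, at 0.20 (limma adjusted p = 0.0485). Kit, the stem cell factor receptor, was 2.17-fold lower at 8.88 ± 1.15 RPKM in OMP, and the transcription factor gene Myb was 1.34-fold lower. Of 28 tested genes 6 rose and 10 fell, or 6 and 12 when adjusted over the list alone. The median was 0.04 and the mean -0.06. Camera gave an upward direction and did not call the list (adjusted p = 0.827), while fry gave a downward one (fry adjusted p = 0.00445).

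Nucleotide and one-carbon genes moved in both directions. Tk1 (thymidine kinase) fell from 42.1 ± 1.30 to 16.6 ± 1.88 RPKM, Tyms (thymidylate synthase) was 2.16-fold lower and Shmt2 (mitochondrial serine hydroxymethyltransferase) 1.31-fold lower. Of 34 tested purine and pyrimidine genes 8 rose and 16 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.655). Of 21 serine, glycine and one-carbon genes 3 rose and 12 fell, or 3 and 13 when adjusted over the list alone (camera adjusted p = 0.278). Neither list was called.

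Genes of cholesterol synthesis fell. Acat2, an acetyl-CoA acetyltransferase, was 2.92-fold lower (12.7 ± 0.911 to 4.06 ± 0.653 RPKM) and Cyp51, lanosterol demethylase, was 1.58-fold lower. Of 24 tested genes 0 rose and 20 fell, with the same counts when adjusted over the list alone, and the median was -0.53 (camera adjusted p = 5.15e-05, and adjusted p = 0.0640 with an estimated correlation).

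The tested genes of the NF-kB and inflammatory cytokine list rose on balance. Of its 35 members 23 were tested, and Il1a, Il1b, Il6, Cxcl1, Cxcl3, Ccl2 and Ccl5 were among those under the filter. Ccl4, a chemokine, rose 4.88-fold from 72.6 ± 7.02 to 355.6 ± 1.52 RPKM, and Il1rn, the interleukin-1 receptor antagonist, rose 7.60-fold from 2.03 ± 0.386 to 18.7 ± 2.17 RPKM. Of 23 tested NF-kB and cytokine genes 14 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 7.62e-05, and adjusted p = 0.0640 with an estimated correlation). Genes of the immediate-early and handling-stress list, a quality list, also rose on balance in the OMP libraries. Hspa8, a heat shock cognate protein, rose 2.20-fold and Ier2 was 1.75-fold lower. Of 16 tested genes 10 rose and 2 fell, or 10 and 3 when adjusted over the list alone (camera adjusted p = 0.00187, and adjusted p = 0.155 with an estimated correlation). The chaperone genes Hspa5 and Hyou1 of the unfolded protein response rose 1.41-fold and 1.42-fold. Of 20 tested genes of that list 7 rose and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.00345). That call was lost with an estimated correlation (adjusted p = 0.133) and with quantile normalization (adjusted p = 0.0679).

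**Figure D4:**
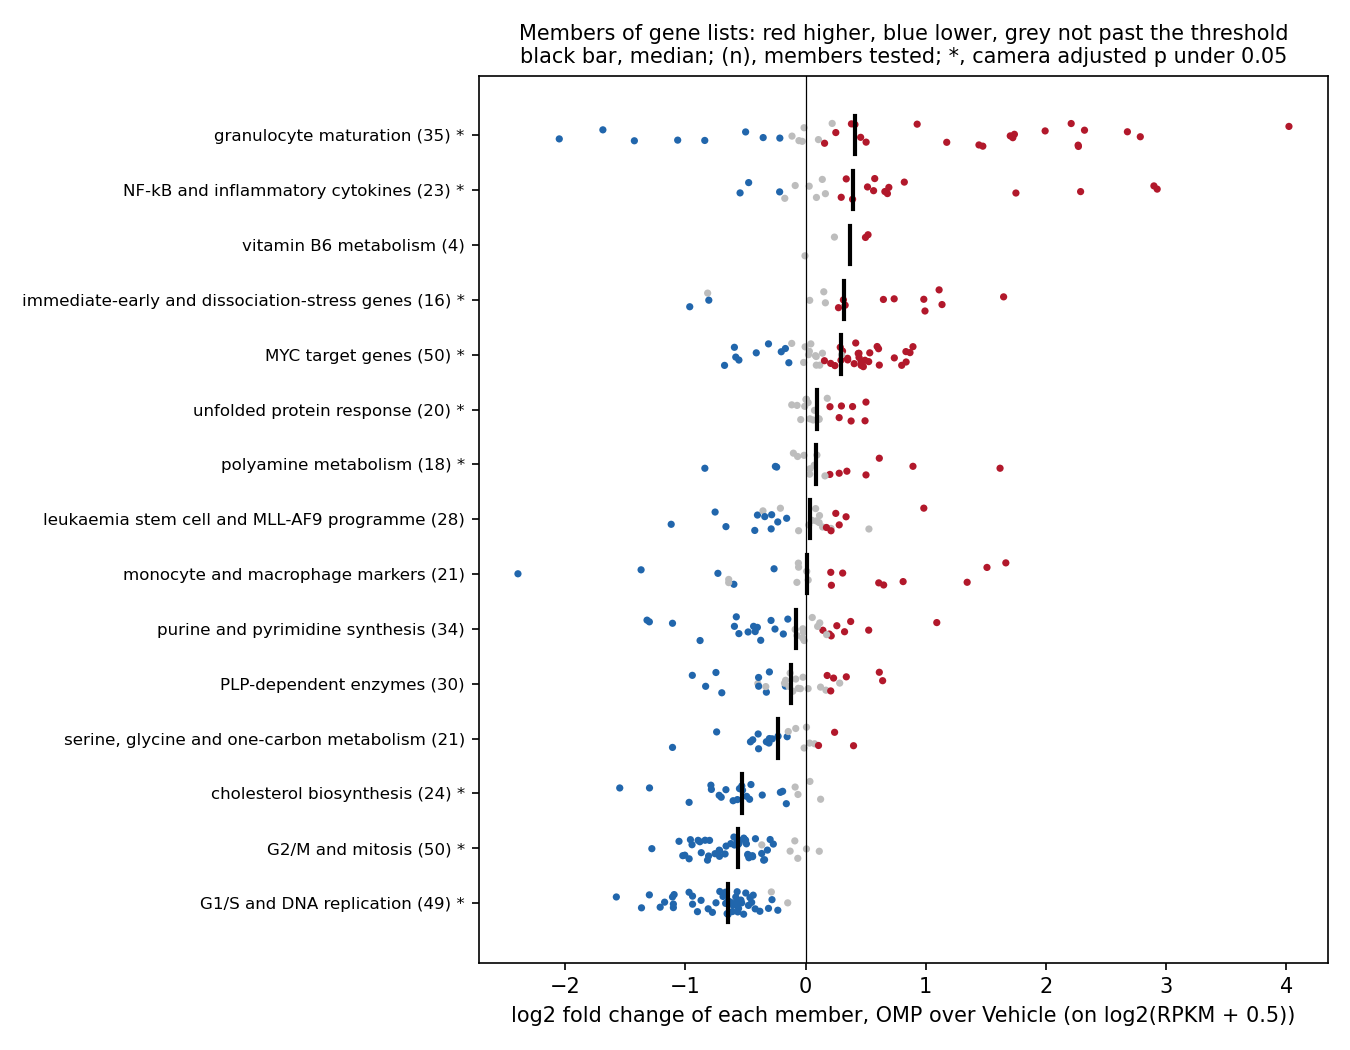
Log2 fold change (horizontal axis, OMP over Vehicle) of each tested member of the 8 lists on the main question and the other called lists, red where higher, blue where lower, grey where not past the threshold, with black bars at the list medians. The medians run from -0.65 for G1/S genes to 0.41 for granulocyte genes, and an asterisk marks lists with a camera adjusted p under 0.05.

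Camera called 9 of the 38 lists, and 3 of these, the 2 cell-cycle lists and the MYC targets, held with an estimated correlation. For the polyamine, cholesterol, NF-kB and unfolded protein lists the estimate (-0.0008, -0.029, -0.032 and -0.022) was under the preset 0.01. Stronger correlation between genes is therefore not why those calls were lost. The estimate was above 0.01 for the granulocyte list (0.087) and the immediate-early list (0.021), but this does not show that correlation lost those calls. For the MYC targets the estimate was also under 0.01 (0.0024), and the camera adjusted p still went from 2.78e-07 to 0.0375. Calls therefore weakened under this setting without stronger correlation, and the share due to correlation was not tested. Markers of other blood cells were mostly under the filter. Of 16 erythroid markers 1 was tested, Tfrc, and of 12 B cell markers 1 was tested. Cytosolic ribosomal protein genes, a quality list, had 8 higher and 36 lower of 77 tested, or 13 and 38 when adjusted over the list alone (camera adjusted p = 0.323). They passed with TPM rescaling (0.0489), quantile normalization (2.32e-05) and voom (0.0174), downward each time. For the RPKM as deposited, the adjusted p was 0.863 with an estimated correlation.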

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

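The 4 alternatives on recovered reads, thinning, short features and GC content were chosen after seeing the data. Leaving out each library in turn gave 3968 to 4241 changed genes, of which 3805 to 3995 were among the 4735 of the main comparison, and no gene called in both changed sign. Over all alternatives to the processing, 3968 to 5336 genes were called. The 5336 came from voom, which kept 4544 of the main calls. Quantile normalization kept 3936, of which 3 changed sign, and 0 changed sign under each of the others. With at least 2-fold change required, 424 genes remained (180 higher, 244 lower), and at an adjusted p under 0.01, 3070 (1079 higher, 1991 lower), by construction of the thresholds. The 9 called lists became 3 with an estimated correlation and 29 with fry, which does not compare a list with other genes, and were 8 to 11 elsewhere. Fry gave the leukaemia programme a downward direction (fry adjusted p = 0.00445) and camera an upward one without a call (list median 0.0397, mean -0.060). The mean was below 0 but above the median of -0.089 over all genes tested. Camera compares a list with other genes, but by test statistics, so these fold changes do not settle why the directions differ. Lists past the threshold in neither test were given no direction. For the named genes, 900 of the alternative values kept their side of the threshold, 1 lost it, 5 gained it and 0 reversed. For genes chosen after their values were seen, 1483 values kept their side, 43 lost it, 41 gained it and 1 reversed. The reversal was Hsp90ab1 under quantile normalization (-0.12), and the cause was not tested. The replicate numbers share only a number. Deviations of same-numbered libraries correlated at -0.0024, 0.015 and 0.0069, and the libraries did not each correlate best with their own number. With the replicate block 4445 genes were called (1598 higher, 2847 lower) and 9 lists. Depth limits the short features, of which 33 of 162 under 200 bp were called.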

Other observations

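The explanations and gene groups in this part were chosen and tested after the results had been seen, except the counts over other splits of the libraries. Members of the gene groups were chosen after their values were seen, so counts of rises and falls within a group are no independent test. Genes of the stefin A cluster, a group of near-identical cysteine protease inhibitor genes, rose together. All 9 tested members rose, with a median log2 fold change of 2.39, and Stfa1 went from 2334 ± 51.9 to 8359 ± 389 RPKM. The cluster took 0.335% ± 0.0064 of the recovered library total in Vehicle and 1.21% ± 0.045 in OMP (SD, n = 3). Which copies the reads came from is uncertain. Of 16 tested genes of fatty acid synthesis and desaturation, 8 fell and 1, Elovl1, rose, with Scd2 falling from 212.1 to 112.1 RPKM and Fads1 from 33.1 to 14.6 RPKM, while Fasn stood at 60.5 and 62.6 RPKM.

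Kmt2a, the native gene of the MLL part of the fusion, rose from 73.1 to 121.5 RPKM and Mllt3, its AF9 partner, from 49.4 to 74.5 RPKM. Nras stood at 154.5 and 169.3 RPKM, and passed the threshold with median-of-ratios scaling but not in the main comparison. The table does not separate reads of a construct from those of the native gene. Among stress genes picked after their values were seen, Cdkn1a rose from 78.3 to 135.2 RPKM while Ddit3 fell from 115.7 to 63.5 RPKM. The lists they belong to were not called. Of 30 tested p53 targets 9 rose and 5 fell (camera adjusted p = 0.186). Of 45 tested genes of the ATF4 and amino-acid response 10 rose and 20 fell (camera adjusted p = 0.517). Of 21 cytosolic and mitochondrial chaperone genes 9 rose and 5 fell, and their median of 0.08 was -0.0034 with TPM rescaling.

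The real grouping gave 4735 changed genes and 1 of the 10 splits gave as many, the real one, where the highest other split gave 1 gene. For gene lists the real grouping gave 9 and the highest other split 6, and again 1 split gave as many. With 10 splits the share is never under 0.1, too few to test chance.

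More genes were lower than higher with OMP, with a median log2 fold change of -0.089 over all genes. A larger share of reads in a few abundant genes would lower all others. The 20 genes with most reads over all libraries held 5.10% of reads in Vehicle and 6.16% in OMP. They give an expected shift of -0.016, less than 0.5 of the observed median. These genes were picked by total reads and not by gain, so gains spread over other genes are not covered. With reads thinned to equal totals 35.8% of calls were higher against 35.9%, so unequal counting noise between the groups does not account for the split. RPKM already divides by the library total, so thinning could hardly move the folds and tests no more of depth than this. The scaling itself stays open. Median-of-ratios scaling gave 51.4% higher and removal of the trend with GC content and length 53.3%, but both centre each library and so bring the split towards balance by construction. The labels name no spike-in that would set the level of total RNA, and an effect of OMP on it was not tested.

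Cell-cycle genes fell while MYC targets rose, with a gap of 0.94 between the medians of the MYC and G1/S lists. The gap was 0.90 with the trend with GC content and length removed, which argues against GC content or length as the whole cause. It was 0.95 with reads thinned to equal totals. As RPKM already divides by the library total, thinning could hardly move the gap, and no conclusion on depth is drawn from it. A response of the cells to OMP stays open and was not tested further. Slower division, a change in cell types and a direct effect are not separated by these data.

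Azurophil granule genes fell while specific and gelatinase granule genes rose. All 5 of the former fell (median -1.43) and of 12 of the latter 9 rose and 1, Hp, fell (median 1.57). The former group includes Ms4a3, a membrane protein gene, which had its smallest fall (log2 fold change -0.43). The gap of 3.00 between the medians was 2.98 with the GC and length trend removed, which argues against that trend. Whether all cells or a part of them changed cannot be read from bulk RNA. The receptor gene Csf3r fell from 18.7 to 14.5 RPKM and Cxcr2 stood at 1.59 and 1.56 RPKM.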
